A study of Homo sapiens with 5 samples.

How the data were processed

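Total RNA of MDA-MB-231 cells was sequenced by the authors in 5 libraries, 1 for each of mock, CGI-1746, LU-102, CGI-1746 plus LU-102 and bortezomib, after 4 h of treatment. Per the labels, RNA was extracted with a Qiagen kit and sequenced by a service company with 150 bp paired reads and 40000000 reads planned per library. The authors' processing notes name Partek and hg38. Versions, the aligner, the annotation, the filter, the strand and the normalization are not given in the sources used here.

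The deposited table gives a normalized expression signal per gene and library, called a least squares mean in its header, whose scale is not stated. It holds 4202 genes, each with 5 levels that sum to at least 5.04, and a column named for total counts that equals this sum. Columns that repeat a library in another comparison were identical to the column used, and 7 such columns were not used here. The ratio columns, per the file headers, divide the signal of the first condition by that of the second. The p-value and FDR columns were deposited by the authors. The p-value equals a Poisson Wald test that takes the levels as counts, with a largest difference of 2.6e-05 over the 6 comparisons.

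The unit of the levels was examined on short RNA genes of a single exon. For these, level times gene length was a multiple of 0.5 times 1 value per library, so the levels are reads divided by gene length and by a library factor. Each read of such a gene adds 59.3 to level times base pairs in mock, 58.8 with CGI-1746, 58.5 with LU-102, 58.8 with the combination and 53.8 with bortezomib. Of 31 such genes, 30 or 31 lay within 0.1 of a whole number in each library when counted in units of 0.5 reads. If the levels are RPKM, which is not stated, the libraries held about 16900000, 17000000, 17100000, 17000000 and 18600000 reads in the same order. Reads of short RNAs were recovered this way, and ratios were given exact Clopper-Pearson intervals at 95%, which cover counting error only. Reads behind mRNA levels are known only roughly, since the transcript lengths used by the authors are not given: about 2600 for HSPA1B, 57 for HSPA6, 140 for HMOX1 and 950 for CYP1B1 in mock.

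Every library was compared on log2(level + 1), with the pseudocount of 1, among genes with a level of at least 1 in either library. A gene was counted at a ratio of 2-fold or more on that scale. With 1 library per condition there is no replicate error, so no test across genes was run. The 8 comparisons were each treatment against mock, the combination against each single agent and against bortezomib, and LU-102 against bortezomib. Departure from additivity was the log2 value of the combination less those of both single agents plus that of mock, with a threshold of 1. A robust spread of it across genes, taken in bins of level, gave a median SD of 0.0967 for the log2 ratio of 2 libraries. It holds any interaction of the inhibitors but gives little weight to genes with large departures.

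Before the data were examined, 31 gene lists, the genes to be named, the comparisons, the thresholds and most alternatives were fixed. The genes named are the 10 highest and 10 lowest of each treatment against mock among genes with a level of at least 5 in either library, and up to 4 members of each list among those changed 2-fold in any treatment. To these come the 5 highest and 5 lowest departures among genes with a level of at least 5, the genes of cell identity, BTK with related kinases and the catalytic proteasome subunits. Other genes were chosen after their values were seen, among them DUSP4, IFIT3, SNORA38, SNORA79B, SNORA67, RNU6ATAC, SNORA7B and SCARNA1. Values of a few single genes are not reported here. Of the lists, 22 had at least 5 measured genes. Their medians were placed among 10000 random lists of the same size, drawn from 10 bins of mean expression. With 22 lists a comparison, about 1 list is outside the central 95% by chance if the genes of a list vary independently. Genes of a list that move together between cultures would raise this number, by an amount that single libraries cannot show.

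Likeness was given as Pearson and Spearman correlations across genes, with bootstrap intervals over 1000 resamples and 100 simulated sets of unchanged libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are those of GRCh38.p14, counted from 1, and symbols of 4126 of the 4202 genes matched RefSeq, 3913 of them protein-coding. GC content and transcript length came from GENCODE 29.

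The rule was tested on simulated data built like the combination and mock libraries, over 20 runs. The changed genes were drawn from those with a level of at least 5 in mock, which 1338 of 4202 genes reached. Lower levels, where the pseudocount shrinks ratios more, were not covered. Of the drawn genes changed 1.5-fold 0% were called, of those changed 2-fold 22.4%, of those changed 3-fold 99.9% and of those changed 4-fold 100%. A true 2-fold change was recovered at a median log2 value of 0.90, since the pseudocount shrinks low levels. No gene among 4002 left unchanged was called. This followed from the setting, as the simulated noise of a log2 ratio had an SD of at most 0.116, far below the threshold of 1. The larger counting error of short RNAs with few reads was not simulated, so false calls among them are not bounded. Of 400 unchanged lists, 3% lay outside the central 95% of random lists. These lists were random genes with independent noise, so lists whose genes move together were not covered.

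The alternatives were pseudocounts of 0.25 and 5, no level filter, a level of at least 5, 2 other scalings between libraries, 20 expression bins and rank correlation. List medians under the alternatives were placed among fewer random lists than in the main run. Added after the data were seen were scaling without the bortezomib library, protein-coding genes only, matching without the bortezomib library, and a regression on GC content, its square, log length and level. In that regression squares of length and level were first included and then left out, as in the form written beforehand, which moved a correlation of residuals only slightly. Scaling by trimmed means needs counts, which were not used here.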

Results

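Gene expression was measured by total RNA sequencing in MDA-MB-231 cells, a triple-negative, mesenchymal-like breast cancer line. The cells were kept for 4 h with no inhibitor (mock), with CGI-1746, with LU-102, with both, or with bortezomib. CGI-1746 is named a BTK inhibitor in the title of the series, BTK being a kinase of B cell receptor signalling. LU-102 is an inhibitor given alone and with CGI-1746, and bortezomib, a proteasome inhibitor, served as the control for pathways that proteasome inhibition changes. Each of the 5 conditions has 1 library, so no value below has a replicate error and no difference was tested. The deposited table lists 4202 genes, and the 5 levels of each listed gene sum to at least 5.04. The levels summed to 99255 in the mock library, 100684 with CGI-1746, 126120 with LU-102, 124373 with the combination and 135512 with bortezomib. A few genes, largely short RNAs, made up most of each sum: the 5 most abundant genes held 55.9% in mock, 56.7% with CGI-1746, 65.9% with LU-102, 61.6% with the combination and 73.8% with bortezomib. These are shares of summed levels and not of reads, since levels are divided by gene length and short genes weigh more in them. With bortezomib the 5 most abundant genes included RNA45SN3 at a level of 13832, a long gene of the 45S ribosomal RNA precursor. It also holds the sequences of mature ribosomal RNA. A level of at least 1 was reached by 4161, 4170, 4171 and 4177 genes in the first 4 libraries in that order, and by 2231 genes in the bortezomib library.

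The mesenchymal genes of this line were well expressed in mock. VIM, an intermediate filament gene, had a level of 92.1, LGALS1, a galectin, 48.4, AXL, a receptor tyrosine kinase, 17.7, and S100A4, a calcium-binding protein, 17.3. CAV1 of caveolae had 9.64, MSN, which links actin to the membrane, 5.68, CD44, a hyaluronan receptor, 4.91 and SNAI2, a repressor of epithelial genes, 4.85. Of the luminal keratins KRT18 had 35.6 and KRT8 2.02. Differences of these mesenchymal genes from mock were small outside the bortezomib library, with list medians of -0.06 with CGI-1746, -0.11 with LU-102 and -0.02 with the combination on the log2 scale, and -1.77 with bortezomib. BTK, TEC, BMX and TXK, which are related kinases, were not analysed here, nor were marker genes of blood and endothelial cells, mitochondrially encoded genes and PSMB7.

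CGI-1746 against mock asked what the BTK inhibitor does on its own. Among protein-coding genes 2 heat shock genes stood highest: HSPA1B and HSPA1A, which encode the inducible HSP70 chaperone, were both 1.11 higher on the log2 scale. HSPA1B (chromosome 6, 31827738 to 31830254) had a level of 136 against 62.2, and HSPA1A (chromosome 6, 31815543 to 31817942) 52.7 against 24.0. CYP1B1, a cytochrome P450 gene (chromosome 2, 38067509 to 38076151), was lower by log2 -1.02, at 4.76 against 10.7. In all, 5 genes were 2-fold or more higher and 2 lower among the 4186 compared, and the rest of these were small nucleolar RNAs. The coding sequences of HSPA1A and HSPA1B are nearly identical, so the share of each of these 2 genes is uncertain.

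Across the 20 measured heat shock genes the median with CGI-1746 was 0.10, the 100th percentile of matched random lists, and 19 of the 20 lay above 0. Without the HSPA1 genes and HSPA6 the median was 0.05, at percentile 97.4, inside the central 95% of random lists. HMOX1, the heme oxygenase of the NRF2 response, was 0.92 higher, DDIT4, an inhibitor of mTORC1 signalling, 0.87 higher, IFIT2, an interferon-induced gene, 0.72 higher, and NEAT1, the RNA of paraspeckles, 0.60 higher. DUSP5, an ERK phosphatase, was 0.55 higher and TXNIP, which binds thioredoxin, 0.53 higher. Metal response genes, the metallothioneins, had a median of 0.29 (99.99th percentile), and ATF4 and CHOP targets one of 0.08 (98.7th). NRF2 targets had 0.05 (97.7th percentile), a place lost under 6 of the alternatives, among them a pseudocount of 5 (97.25th). The lowest of these was the 96.75th percentile, near the bound. Alternatives drew fewer random lists, so these losses can lie partly in the drawing.

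Genes of ERK feedback were lower with CGI-1746, at a median of -0.24 over 8 genes, below all random lists. DUSP6, an ERK phosphatase, was lower by log2 -0.37 and DUSP4, another, by -0.32, while DUSP5 went the other way. The G2 and M phase genes had a median of -0.11 (0.81st percentile) and the apoptosis regulators -0.11 (1.2nd). CXCL8, a neutrophil chemokine, and IL11, a cytokine, were both lower at -0.45, NOG, a BMP antagonist, at -0.49 and AJUBA, a LIM protein of Hippo signalling, at -0.42. ADO, a thiol dioxygenase, stood at -0.41, and ENC1, an actin-binding protein, and SOWAHC at -0.39.

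The short RNAs past 2-fold with CGI-1746 rested on few reads. SNORA38, a guide of rRNA modification, had 34 reads against 15, a ratio of 2.25 with a 95% interval of 1.19 to 4.44. SNORA71A had 10 against 2 reads and SNORA71D 6 against 1, and the interval of SNORA71D, 0.722 to 274, holds no change. SNORA81 had 4 against 16 reads, a ratio of 0.248 with an interval of 0.0603 to 0.769. SNORD15B had 53 against 78 reads, and RNVU1-7, a U1 variant, was 0.55 higher.

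LU-102 against mock asked the same of the second inhibitor. No protein-coding gene was 2-fold different, and heat shock genes stayed at a median of -0.05 (51.8th percentile), with 9 above 0 and 11 below. HSPA1B and HSPA1A were among those above 0, at levels of 79.7 against 62.2 and 31.6 against 24.0. Their ratios to mock were 1.28 and 1.32. The 3 genes past the threshold, of 4193 compared, were small nucleolar RNAs and all were higher. SNORD3A, the U3 RNA of rRNA processing, was 1.08 higher at a level of 48.5 against 22.5, which was 180 reads against 82, a ratio of 2.16 with an interval of 1.66 to 2.85. SNORA71A was 1.24 higher and SNORA71D 1.47 higher, on 8 and 7 reads against 2 and 1.

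The other high genes with LU-102 were largely short RNAs: SNORD10 at 0.82, SNORD3D at 0.69, RNVU1-6 at 0.60 and SCARNA10 at 0.58. RN7SL3 and RN7SL2, RNAs of the signal recognition particle, were 0.77 and 0.66 higher, and RPPH1, the RNA of RNase P, 0.73 higher. CCDC85B, a repressor of transcription, and MRPS34, a mitochondrial ribosomal protein, were 0.62 higher. The low end held the short RNAs SNORD15B at -0.84, SNORA81 at -0.68, SCARNA13 at -0.53 and SCARNA7 at -0.47. It also held TCEAL9 at -0.50, SPANXB1 at -0.42, SOWAHC at -0.41, C6orf120 and SPCS3, a signal peptidase subunit, at -0.40 and KLF10, a TGF-beta induced repressor, at -0.40. Replication-dependent histones had a median of 0.20 (100th percentile) and metal response genes 0.16 (99.2nd, or 95.9th with a level of at least 5). The 27 measured proteasome subunits had 0.01 (96.7th percentile), and 0.07 (99.97th) after adjustment for GC content, length and level. That adjustment also moved ribosomal protein genes to 0.05 (100th percentile), immediate early genes to -0.11 (0.16th) and endoplasmic reticulum chaperones to -0.07 (0.62nd).

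The combination against mock asked what both inhibitors do together. Heat shock genes were again highest among protein-coding genes, and now 4 of them passed 2-fold. HSPA1B reached a level of 284, a log2 ratio of 2.17, and HSPA1A 107, a ratio of 2.11. DNAJB1, the HSP40 partner of HSP70 (chromosome 19, 14514769 to 14560391), was 1.08 higher at 23.7 against 10.6. HSPA6, an HSP70 gene expressed under stress (chromosome 1, 161524540 to 161526894), had 6.30 against 1.43. With a pseudocount of 5 DNAJB1 was 0.87 and HSPA6 0.81 higher, both under 2-fold, and DNAJB1 was also under it with median-of-ratios scaling, at 0.97. HMOX1 (chromosome 22, 35381096 to 35394207) was 1.41 higher at 13.5 against 4.44, and CYP1B1 was again lower, at 4.39 and log2 -1.12. With a pseudocount of 5 these were 0.97 and -0.74, both under 2-fold.

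All 20 heat shock genes lay above 0 with the combination, and their median was 0.32 (100th percentile). MT1X and MT2A, metallothioneins, were 0.97 and 0.95 higher, and metal response genes had a median of 0.65 (100th percentile). DDIT4 was 0.94 higher, ATF4 and CHOP targets had 0.21 (99.1st percentile) and NRF2 targets 0.23 (99.9th). Replication-dependent histones had 0.20 (98.4th percentile), which became -0.01 once GC content, length and level were adjusted for. NRF2 targets were at the 96.6th percentile with a pseudocount of 5.

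ERK feedback genes had a median of -0.22 (0.01st percentile) with the combination. DUSP6 was lower by log2 -0.64, PHLDA1, which is induced by growth factors, by -0.51 and SPRY2, an ERK pathway inhibitor, by -0.48. CXCL8 stood at -0.62, GPR65, an acid-sensing receptor, at -0.50, IL24, a cytokine, and ENC1 at -0.49, and ZBTB18, a transcription repressor, at -0.46. The G2 and M phase genes had -0.13 (0.03rd percentile), NF-kB targets -0.08 (1.44th) and YAP and TEAD targets -0.11 (0.40th). With a level of at least 5 NF-kB targets had 0.080 (60.6th percentile), and after adjustment for GC content, length and level YAP and TEAD targets were at the 4.25th percentile, so neither place was firm. The 9 genes past 2-fold, of 4189 compared, were 7 higher and 2 lower, and 3 of them were short RNAs. SNORA71D had 14 against 1 reads and SNORA7B 7 against 2, while SCARNA1 had 1 against 5, a ratio of 0.198 with an interval of 0.00419 to 1.77. SNORD3A was 0.83 higher, and SNORA81 stood at -0.94.

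**Figure D1:**
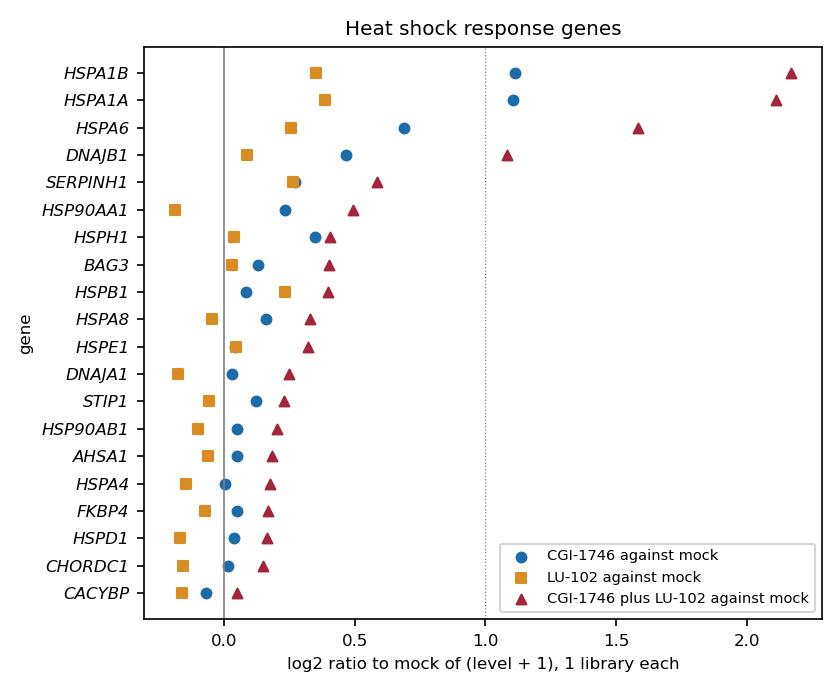
Log2 ratio to mock of the heat shock genes, each point 1 gene with CGI-1746, LU-102 or both, and the dotted line at 1 marks 2-fold. HSPA1B and HSPA1A stood highest with the combination, at 2.17 and 2.11, and most other members lay closer to 0.

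**Figure D2:**
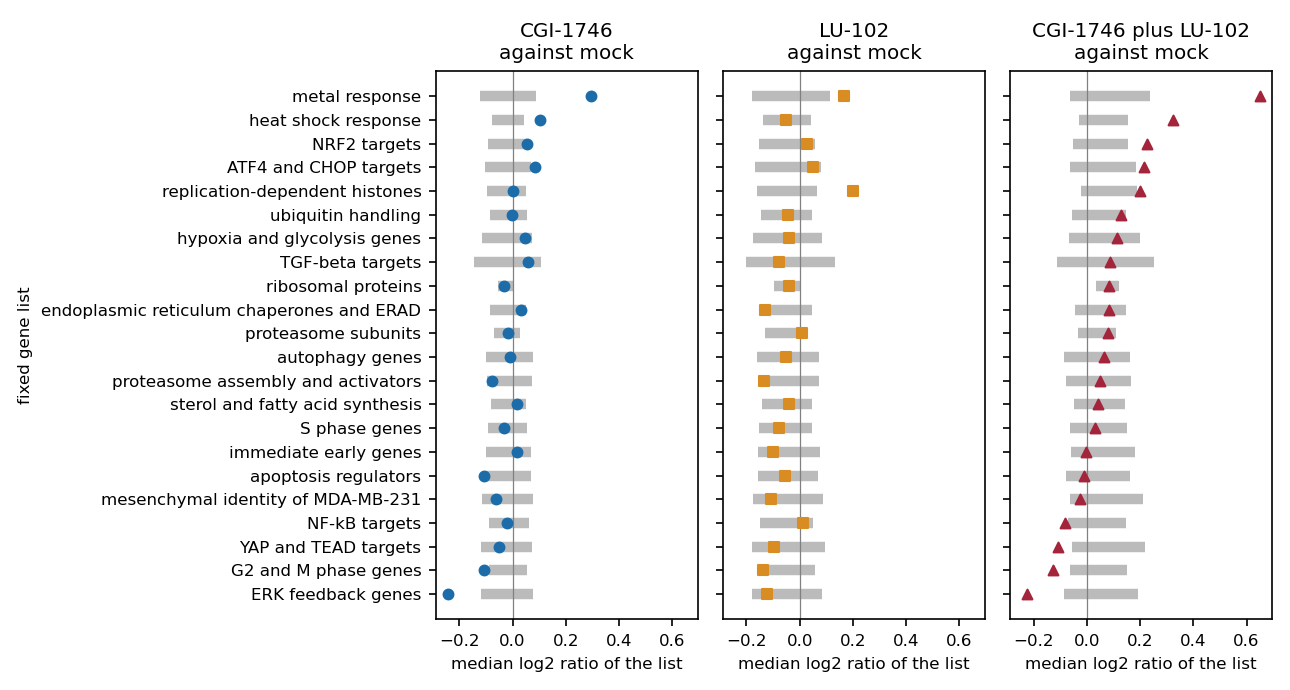
Median log2 ratio to mock of each fixed gene list with CGI-1746, LU-102 and the combination, with the central 95% of random lists matched on expression as grey bars. Heat shock genes lie above the bars with CGI-1746 (0.10, or 0.05 and inside the band without the HSPA1 genes and HSPA6) and the combination (0.32), and ERK feedback genes lie below them (-0.24 and -0.22).

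The combination was set against each single agent to see what each inhibitor added. Added to LU-102, CGI-1746 went with higher HSPA1B at 1.82, HSPA1A at 1.73, HSPA6 at 1.33 and HMOX1 at 1.19. The remaining 2 of the 6 genes past 2-fold were SNORA79B at 1.08 and SNORA67 at 1.05, and none was lower. SNORA79B had 7 reads against 2 and SNORA67 19 against 8, with intervals of 0.670 to 34.7 and 0.998 to 6.31 that hold no change. With a pseudocount of 5 only HSPA1B and HSPA1A stayed past 2-fold, and HSPA6 and HMOX1 fell under it. The all-gene median of this comparison was 0.08 as deposited and -0.02 with median-of-ratios scaling. Heat shock genes had a median of 0.33 (100th percentile), endoplasmic reticulum chaperones 0.23 (100th), metal response genes 0.43 (100th), ATF4 and CHOP targets 0.21 (99.4th), proteasome assembly genes 0.19 (99.2nd) and NRF2 targets 0.16 (97.8th). With a pseudocount of 5 ATF4 and CHOP targets fell to the 96.85th percentile and NRF2 targets to the 86.8th. ERK feedback genes had -0.13, below all random lists, and YAP and TEAD targets -0.10 (0.03rd percentile). NF-kB targets, G2 and M phase genes and histones stood low among random lists at medians within 0.02 of 0, the last 2 fell below 0 under other scalings, and NF-kB targets had 0.046 (14.8th percentile) with a level of at least 5.

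Added to CGI-1746, LU-102 went with a further higher level of HSPA1B, at 1.06, and HSPA1A, at 1.01. The other 2 genes past 2-fold were RNU6ATAC, an RNA of the minor spliceosome, at 1.19 and SCARNA1 at -1.96. RNU6ATAC had 5 reads against 1, with an interval of 0.560 to 237 that holds no change, and SCARNA1 had 1 read against 12. With median-of-ratios scaling only these 2 short RNAs stayed past 2-fold, and HSPA1B and HSPA1A both fell under it. The proteasome subunits had a median of 0.12 (99.5th percentile), with 22 of 27 above the all-gene median. Heat shock genes had 0.20 (100th percentile), metal response genes 0.42 (100th), NRF2 targets 0.18 (99.8th) and histones 0.20 (99.2nd). NF-kB targets had -0.09, below all random lists, ERK feedback genes -0.08 (0.17th percentile), immediate early genes -0.05 (0.245th), G2 and M phase genes -0.03 (0.46th) and YAP and TEAD targets -0.02 (1.33rd). The all-gene median was 0.04 as deposited and -0.06 with median-of-ratios scaling, so list medians near 0 have no firm sign. With a level of at least 5 NF-kB targets had 0.058 (38.98th percentile), YAP and TEAD targets 0.015 (4.67th) and proteasome subunits 0.11 (82.2nd). After adjustment for GC content, length and level histones had 0.03 (89.05th percentile) and G2 and M phase genes -0.05 (3.85th).

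Departure from additivity asked whether the combination differed from the sum of the 2 single effects. Heat shock genes had a median of 0.27 (100th percentile) against 0.10 for all 4197 genes, and 17 of the 20 lay above that all-gene median. HSPA1B departed by 0.71 and HSPA1A by 0.62, both under the threshold of 1. Proteasome assembly genes had a median of 0.23 (99.4th percentile), endoplasmic reticulum chaperones 0.21 (98.4th), NF-kB targets -0.02 (1.01st) and histones 0.01 (0.58th). With a level of at least 5 NF-kB targets had 0.088 (32.42nd percentile) and endoplasmic reticulum chaperones 0.14 (48.1st), and after adjustment proteasome assembly genes were at the 96.45th percentile. Among genes with a level of at least 5 the highest departures were those of SNORD15B at 1.47, SNORA81 at 1.19, H4C11, a histone, at 0.89, and YDJC and HSPA1B at 0.71. The lowest among the same genes were SCARNA5 at -0.81, RNVU1-7 at -0.71, GPS2, a corepressor subunit, at -0.61, SCARNA10 at -0.57 and FLG, filaggrin, at -0.56. Over all genes compared, 3 were higher and 3 lower by 1 log2 unit or more, all of them short RNAs, and noise cannot be separated from interaction in single libraries.

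**Figure D3:**
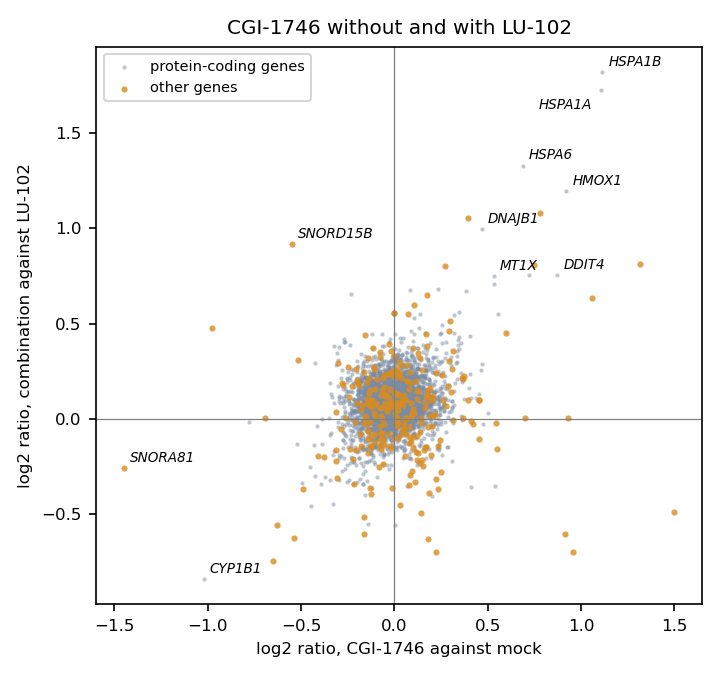
Log2 ratio of each gene with CGI-1746 against mock (x axis) and with the combination against LU-102 (y axis), 2 estimates that share no library, with protein-coding genes in grey and other genes in orange. HSPA1B lies at 1.11 and 1.82 and CYP1B1 at -1.02 and -0.84.

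Bortezomib against mock served as the proteasome inhibitor control. Messenger RNA took a smaller part of this library: the median log2 ratio over 4189 genes was -0.98 as deposited and -0.44 with median-of-ratios scaling. As deposited, 58 genes were 2-fold or more higher and 2015 lower, which became 208 higher and 727 lower with median-of-ratios scaling. The factor of that scaling came from genes with a level of at least 5 in every library, which leaves out genes that fell below it with bortezomib. Counted relative to the all-gene median, 315 genes were higher and 328 lower. Histone genes were lowest: H2BC17, a histone H2B gene, went from a level of 514 to 2.65, a log2 ratio of -7.14. H2BC11, H2BC4, H2BC15, H2BC13, H2BC3, H2AC20, H2BC14 and H2BC6 followed, between -6.62 and -4.13, together with RPL19, a ribosomal protein gene, at -4.14. RMRP, the RNA of RNase MRP (chromosome 9, 35657750 to 35658019), had 3026.5 reads against 37954, a ratio of 0.0723 with an interval of 0.0696 to 0.0750.

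Short nuclear RNAs stood at the high end with bortezomib. SNORD3D and SNORD3A, both U3 RNAs, were 5.85 and 5.21 higher, RNU12 of the minor spliceosome 5.19 and RNU4-2, a U4 RNA, 4.21. RNA45SN2 and RNA45SN3, genes of the 45S ribosomal RNA precursor, were 4.69 and 4.43 higher, SNORA71D 4.95, SNORA71A 4.31, SNORD17 4.21 and SNORD97 4.13. The 45S genes also hold the sequences of mature ribosomal RNA, so precursor and mature RNA cannot be told apart in these levels. Over 34 small nucleolar RNAs the median was 1.79, over 8 small nuclear RNAs 1.54 and over protein-coding genes -0.99. The 13 small Cajal body RNAs, which guide changes of small nuclear RNAs, went both ways, with 4 of them 2-fold or more higher, 4 lower and a median of 0.24. The copies of the 45S genes and of SNORA71 are nearly identical, so the share of each copy is uncertain.

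**Figure D4:**
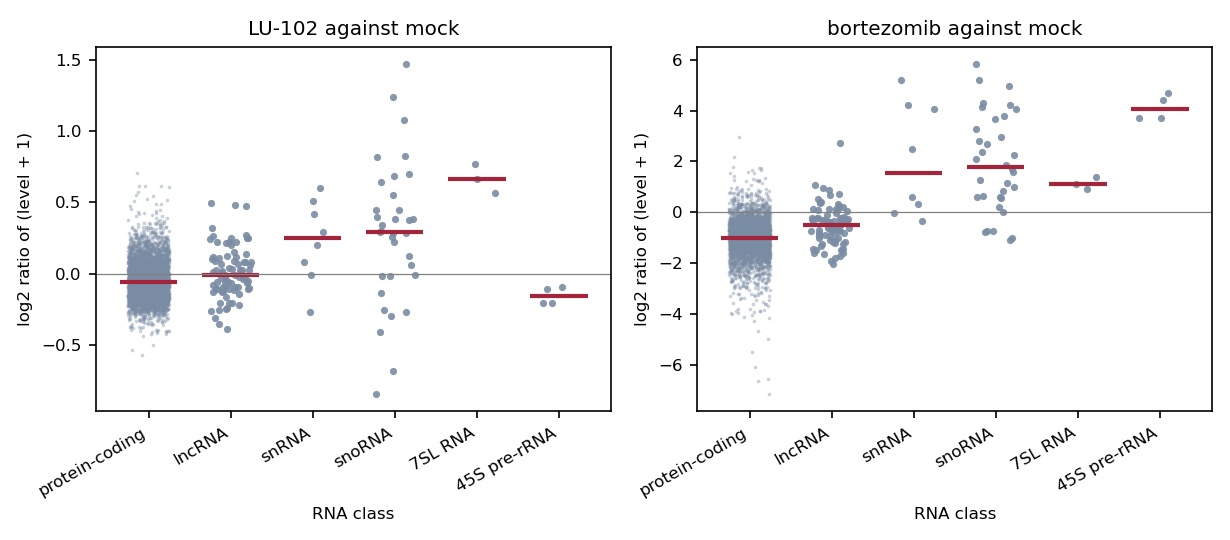
Log2 ratio to mock by class of RNA with LU-102 and with bortezomib, on different scales, each point 1 gene and each line the median of its class. The median of small nucleolar RNAs was 0.30 with LU-102 and 1.79 with bortezomib, and that of protein-coding genes -0.99 with bortezomib.

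Gene groups also differed from one another with bortezomib. Relative to the all-gene median, CXCL8 was 1.88 higher (level 29.7 against 15.4), CEBPB, a transcription factor of stress and inflammation, 2.31 higher, HSPA6 2.14, HMOX1 1.67, HSPA1B 1.65 and FOSB, an immediate early gene, 2.25. HSPA1A was 1.62 higher, but 14 of the 20 heat shock genes were below that median, HSPA8, the constitutive HSP70, stood at -2.28 relative to it, and the list median was -1.34 (27.2nd percentile). All 13 NF-kB targets lay above the all-gene median, and their median was -0.07 as deposited (100th percentile) and 0.63 with median-of-ratios scaling. ATF4 and CHOP targets had -0.50 (98.9th percentile), or 0.26 with that scaling, while DDIT3, which encodes CHOP, stood at -2.05. Histones had -3.49, G2 and M phase genes -2.00 and ribosomal protein genes -2.05, each below all random lists, and proteasome subunits -1.46 (0.515th percentile, or 2.88th after adjustment for GC content, length and level), with PSMD2 lowest at -2.65. UBB, which encodes polyubiquitin, stood at -2.77.

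The catalytic proteasome subunits changed little outside the bortezomib library. PSMB5, the chymotrypsin-like subunit, had levels of 6.57 in mock, 6.40 with CGI-1746, 6.91 with LU-102, 6.66 with the combination and 2.08 with bortezomib. PSMB6, the caspase-like subunit, had 12.8, 13.8, 13.6, 16.4 and 2.78 in the same order. As deposited, the other fixed lists with a percentile lay inside the central 95% of random lists in the comparisons with mock, which holds for ubiquitin handling, autophagy, sterol and fatty acid synthesis, S phase, hypoxia and glycolysis, TGF-beta targets and the mesenchymal genes. Their medians with the combination were 0.13, 0.07, 0.04, 0.03, 0.11, 0.09 and -0.02 in that order. Of the lists with under 5 measured genes, the immunoproteasome had 0.08, the ubiquitin genes 0.23, the interferon-stimulated genes 0.42, the p53 targets -0.00 and the luminal markers 0.14.

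LU-102 and the combination were also set against bortezomib, to see how far each resembled the control. The differences followed those of the bortezomib library: H2BC17 was 7.06 higher with LU-102 and 7.11 higher with the combination, and HSPA8 3.22 and 3.59 higher. CXCL8 was lower, at -1.27 and -1.52, and NF-kB targets had medians of 0.17 (0.02nd percentile) and 0.14 (0.01st) against all-gene medians of 0.91 and 0.99. CEBPB was lower than with bortezomib, at -1.07 with LU-102 and -0.78 with the combination. With LU-102, 1805 genes were 2-fold or more higher and 57 lower, and with the combination 2073 were higher and 53 lower. With median-of-ratios scaling these became 657 and 183, and 609 and 192. Counted relative to each all-gene median they were 333 and 269 with LU-102, and 342 and 254 with the combination.

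The likeness of responses was described by correlations across genes, which are not independent replicates. HSPA1B and HSPA1A were 2-fold or more higher in both estimates of the effect of CGI-1746, where overlap by chance would be 0.00717 genes. That value takes genes as independent, which these 2 are not, since their coding sequences are nearly identical. Those estimates, CGI-1746 against mock and the combination against LU-102, share no library and gave a Pearson r of 0.259 (95% bootstrap interval 0.167 to 0.341) and a Spearman rho of 0.134. The 2 estimates for LU-102 gave r = 0.349 (0.291 to 0.404) and rho = 0.362. Unchanged libraries simulated around mock gave -0.0340 to 0.0277. Bortezomib against mock and the combination against CGI-1746 gave r = 0.147 and rho = 0.167, and bortezomib against mock and the combination against LU-102 gave 0.0792 and 0.0362.

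Pairs that share the mock library are alike by construction, at r of 0.477 to 0.520 in simulated unchanged libraries. LU-102 and CGI-1746 gave 0.536, LU-102 and the combination 0.677, and CGI-1746 and the combination 0.657. HSPA1B, HSPA1A and CYP1B1 were among the 4 genes past 2-fold in the same direction with CGI-1746 and with the combination. Bortezomib gave 0.221 with LU-102, 0.176 with CGI-1746 and 0.2497 with the combination, with covariances of 0.0297, 0.0210 and 0.0394 against 0.00474 simulated.

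The authors' deposited table holds tests of 6 comparisons between single libraries. At a false discovery rate of 0.05 it lists 3 genes higher with CGI-1746 than in mock, which were RMRP, HSPA1B and RNVU1-7. It lists 7 higher with LU-102, 14 higher with the combination, and 36 higher and 203 lower with bortezomib. With the combination both HSPA1B and HSPA1A were listed, while with CGI-1746 HSPA1A was not. HMOX1 was listed in none of the 6 comparisons. The deposited p-values treat the normalized levels as counts and hold no variation between cultures.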

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

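The bound of 0.5 used to single out these RNAs was chosen after the values were seen, as were the tests of the bortezomib library and the test of heat shock genes with CGI-1746 alone.

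Of the 203 genes that the naming rule gave, 3 short RNAs went opposite ways with an inhibitor alone and with the same inhibitor added to the other one, by 0.5 or more on the log2 scale each time, and the difference was not tested. SNORD15B, a guide of rRNA methylation, stood at -0.55 with CGI-1746 alone and at 0.92 when CGI-1746 was added to LU-102. It stood at -0.84 with LU-102 alone and at 0.62 when LU-102 was added to CGI-1746. Its reads were 78 in mock, 53 with CGI-1746, 43 with LU-102 and 83 with both. Both reversals of SNORD15B are 1 contrast of the same 4 libraries. SNORA71A stood at 1.24 with LU-102 alone and at -0.75 when added to CGI-1746, on 2, 10, 8 and 5 reads. SNORA81 stood at -0.68 and 0.51, on 16, 4, 9 and 7 reads, and the intervals of these ratios for SNORA71A and SNORA81 all hold no change.

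Heat shock genes were higher with CGI-1746 and most of all in the combination. Reads shared between HSPA1A and HSPA1B are argued against for the combination, since without the HSPA1 genes and HSPA6 the other 17 genes stood at the 100th percentile against LU-102. With CGI-1746 alone those 17 genes had a median of 0.05 at percentile 97.4, just inside the central 95% of random lists. That is too near the bound to tell whether the list stands out there without HSPA1A, HSPA1B and HSPA6. Of all 20 genes, 19 lay above 0 with CGI-1746 alone. Shared reads are therefore not argued against for that comparison. A trend with GC content, length or level is argued against as the whole cause, as the list kept the 100th percentile after regression in the combination against LU-102, at a median of 0.23. A response to CGI-1746, which the design names, and a difference between single cultures both stay open and were not tested, since each condition has 1 library.

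Messenger RNA was lower and most small nuclear and nucleolar RNAs were higher in the bortezomib library, while small Cajal body RNAs went both ways and RMRP and RPPH1 were lower. A single scaling factor is argued against as the whole cause, because the SD of the log2 ratios of protein-coding genes was 6.64 times that of CGI-1746 against mock. Loss of long mRNA is argued against by a Spearman correlation with transcript length of 0.0719 across 3899 genes. A trend with GC content, length and level is argued against as the whole cause among protein-coding genes. Residuals of that regression had an SD still 6.42 times that of CGI-1746 against mock. The regression took up 16.2% of the variance with bortezomib, so a partial trend is not argued against, and short RNAs were not covered. A fault of the single RNA sample cannot be told apart from an effect of bortezomib with 1 bortezomib library. An effect of proteasome inhibition, which the design names, stays among the open explanations and was not tested.

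LU-102 against mock and the combination against CGI-1746 differed in like genes, although they share no library. Different recovery of short RNAs is argued against, since over 3906 protein-coding genes alone r was 0.394. A trend with GC content, length and level cannot be told apart from an effect of LU-102: it explained 44.9% of the variance of LU-102 against mock, and r over the residuals was 0.150 with an interval of 0.104 to 0.192. That value lies between the bounds of 0.1 and 0.2 set beforehand, so most of the likeness went with the trend and a smaller part did not.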

How the results depend on the processing

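The alternatives chosen only after the results were seen were scaling without the bortezomib library, protein-coding genes only, matching without the bortezomib library and the adjustment for GC content, length and level.

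In the comparisons that involve CGI-1746 the heat shock genes kept their direction under all 10 alternatives, while with LU-102 alone their median ranged from -0.06 to 0.03 and with bortezomib from -1.53 to 0.16. Their median ranged from 0.06 to 0.13 with CGI-1746, from 0.21 to 0.36 with the combination, from 0.21 to 0.39 for the combination against LU-102 and from 0.08 to 0.24 against CGI-1746. Their lowest percentiles were 99.95, 100, 100 and 99.9 in that order. Their departure ranged from 0.10 to 0.31, with a lowest percentile of 99.65. HSPA1B ranged from 1.07 to 1.15 with CGI-1746 and from 2.05 to 2.18 with the combination, HSPA1A from 0.99 to 1.14 and from 1.95 to 2.15. CYP1B1 ranged from -1.13 to -0.69 with CGI-1746 and from -1.24 to -0.74 with the combination, and HSPA6 from 0.81 to 1.96 and DNAJB1 from 0.87 to 1.13 with the combination. Among the genes named as highest, lowest or by departure, none with a value of 1 or more in size reversed. Smaller values could not count as reversed, and genes named only from lists were not covered.

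A pseudocount of 5 shrinks low levels and left 525 genes past 2-fold with bortezomib, 0 with LU-102, 1 with CGI-1746 and 3 with the combination. It left 2 for the combination against LU-102, 1 against CGI-1746, 548 against bortezomib, 481 for LU-102 against bortezomib and 1 departure. A pseudocount of 0.25 gave 6 genes with LU-102, 16 with CGI-1746, 15 with the combination, 11 against LU-102, 13 against CGI-1746, 2845 for LU-102 against bortezomib and 12 departures.

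A level of at least 5, which enters fewer genes, gave 1016 genes with bortezomib, 1 with LU-102, 2 for the combination against CGI-1746, 1061 against bortezomib, 947 for LU-102 against bortezomib and 2 departures. The correlation of the 2 LU-102 estimates became 0.455, that of the 2 CGI-1746 estimates 0.405 and that of bortezomib with the combination against CGI-1746 0.291. NF-kB targets changed sign to 0.080 with the combination, 0.046 against LU-102, 0.058 against CGI-1746 and 0.088 in the departure, which placed them at percentiles 60.6, 14.8, 38.98 and 32.42 and ended each call. YAP and TEAD targets against CGI-1746 became 0.015, and histones became -0.017 against LU-102 and -0.011 in the departure. The cause was not tested.

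Median-of-ratios scaling gave 935 genes with bortezomib, 2 for the combination against CGI-1746, 801 against bortezomib, 840 for LU-102 against bortezomib and a correlation of 0.230 for bortezomib with the combination against CGI-1746. It reversed ATF4 and CHOP targets to 0.26 and NF-kB targets to 0.63 with bortezomib, G2 and M phase genes to -0.10 and histones to -0.13 against LU-102, and histones to -0.16 in the departure. Totals without the 20 most abundant genes gave 967, 2, 836 and 864 genes in the same comparisons, and 0.21, 0.59, -0.10, -0.12 and -0.13 for the same lists. Scaling without the bortezomib library gave 2 genes for the combination against CGI-1746, and -0.091, -0.11 and -0.13 for the last 3 lists. These shifts follow from 1 factor per library, which moves the all-gene median.

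Protein-coding genes only gave 0 genes with LU-102, 3 with CGI-1746, 2 for the combination against CGI-1746 and 0 departures, since the others were short RNAs. Rank correlation gave 0.134 for the 2 CGI-1746 estimates. After adjustment for GC content, length and level the correlation of the 2 LU-102 estimates was 0.150, that of the 2 CGI-1746 estimates 0.347 and that of bortezomib with the combination against CGI-1746 0.230. Histones with the combination became -0.0082, and NRF2 targets with CGI-1746 fell to the 96.75th percentile. Lists that gained a place in the outer 5% of random lists were proteasome subunits with LU-102 (0.07) and the combination (0.10), immediate early genes with both (-0.11 and -0.13) and with bortezomib (0.62), and endoplasmic reticulum chaperones with LU-102 (-0.07) and CGI-1746 (0.08). So did ribosomal protein genes with LU-102 (0.05), NRF2 targets with bortezomib (0.45), autophagy genes against LU-102 (0.08) and ATF4 and CHOP targets in the departure (-0.10). Histones against CGI-1746 fell to 0.03 and YAP and TEAD targets with the combination to the 4.25th percentile, so these left the outer 5% of random lists, as did proteasome assembly and endoplasmic reticulum genes in the departure (96.45th and 90.55th).

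Of the list medians, 1183 stayed within the spread, 282 moved without a change of sign that counted and 21 reversed. Of the single genes, 244 values stayed within the spread and 178 moved. No paired analysis was possible because each condition has 1 library. Scaling by trimmed means was not run, since no counts were used here. Depth limits the short RNAs with few reads: at 138 bp 1 read equals a level of 0.430 in mock and 0.390 with bortezomib, so SNORA71D at 1 read in mock has no firm ratio.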

Other observations

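The genes of the first paragraph, the comparisons of RNA classes and the test in the last paragraph were chosen after the values were seen.

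IFIT2 and IFIT3, interferon-induced genes, were 0.72 and 0.41 higher with CGI-1746 and 0.75 and 0.44 higher when CGI-1746 was added to LU-102. TIPARP, a target of the dioxin receptor like CYP1B1, stood at -0.28 with CGI-1746 and -0.31 with the combination, and AHR, the receptor, at -0.19 and -0.32.

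The RNAs made by RNA polymerase III went different ways with bortezomib. RN7SL2, of the signal recognition particle, was 1.13 higher and RN7SK, which binds the kinase P-TEFb, 0.61 higher, while RMRP stood at -3.79 and RPPH1 at -2.42. With LU-102 RN7SL2 was 0.66 and RPPH1 0.73 higher. The median of 34 small nucleolar RNAs was 0.19 with CGI-1746, 0.30 with LU-102 and 0.49 with the combination.

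One hypothesis for the lower mRNA in the bortezomib library was a general stop of transcription, which could remove short-lived mRNA first. The immediate early genes, whose mRNA is short-lived, stood at percentile 92.4 of matched random lists, and their median was -0.71 against -0.98 for all genes. They stood at percentile 98.3 with a pseudocount of 5, 97.525 with median-of-ratios scaling, 97.9 without the 20 most abundant genes in the totals and 99.35 after adjustment for GC content, length and level. These values go against a loss of short-lived mRNA, but members went both ways, with FOSB at 1.27 and FOSL1 at -1.91. The bound for excluding it was raised after the value was seen, from above the 50th to above the outer limit of the central 95% of random lists, which the list as deposited does not pass, so the stop cannot be told apart from other causes.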
